A study of Homo sapiens with 10 samples.

How the data were processed

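Gene expression was measured in cultured human cells on 10 Affymetrix arrays of biotin-labelled total RNA, 1 array per sample, each with a probe set value for 24308 probe sets. Per the labels' treatment protocol, A549 cells received 0.01% DMSO or 32 nM discodermolide, AD32 cells were grown in 32 nM discodermolide, and AD32 4E-BP1 cells received 0.01% DMSO. Groups were taken from the cell line named in the labels. They comprised A549 in DMSO (n = 4), A549 in discodermolide (n = 2), AD32 (n = 3) and AD32 4E-BP1 (n = 1). The labels call the numbered samples biological replicates and do not say how they were grown apart.

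The deposited values are on a log2 scale, judged from their range, and were made by the authors with Affymetrix Expression Console, per the submitters' processing notes. Its version, summarisation method and normalization settings are not given in the sources used here. No value was missing. Array medians lay between 6.50 and 6.63 on the log2 scale and upper quartiles between 8.14 and 8.39. The arrays therefore appear to have been brought to a similar scale before deposit. The 2 lowest upper quartiles were those of A549 DMSO replicate 1 (8.14) and AD32 replicate 1 (8.25). The values carry no detection call and no background estimate, so low levels were read only as low. The number of arrays limits the precision.

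Probe sets were named from the platform annotation. It gave 1 gene for 19262 probe sets and several genes for 1720, and 3326 were unnamed in the table used here. Probe sets with several genes or no name were kept out of the gene tests and fitted separately. The probe set for TUBB3 also names a neighbouring gene, so TUBB3 was not measured as a single gene here. Of 18279 genes, 740 had over 1 probe set, and the probe set with the highest mean over all arrays was used. Gene order along chromosomes was taken for 18249 genes from a table of the GRCh38.p14 assembly. Only neighbourhood was used, since no build is stated for the deposited values.

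Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited log2 values over all 10 arrays. The 4 groups shared 1 residual spread with 6 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. Both comparisons of AD32 4E-BP1 rest on a lone array that is assumed to vary like the other groups. Fixed gene lists, 23 in number, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Fry asks whether a list's genes move one way on balance and does not compare a list with other genes, and its p-values shifted with the order of the design columns. Of 115 list tests, 17 had a median or mean of opposite sign to the camera direction, and 0 of these passed the threshold.

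The tests were checked on simulated data drawn with the real genes' means and residual spreads over 18279 genes, with 200 genes changed. Each gene was drawn independently, unlike genes that vary together on the real arrays. At a log2 change of 1, 47% of changed genes were recovered for A549 in discodermolide against DMSO. The share was 65% for AD32 against A549 in DMSO, 38% for AD32 against A549 in discodermolide, and 18% and 23% for AD32 4E-BP1 against AD32 and against A549 in DMSO. At a log2 change of 2 the shares were 91%, 90%, 85%, 68% and 65%, in the same order.

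The comparisons, lists, alternatives and the rule for named genes were set before the data were examined. Named genes comprised EIF4EBP1, the 10 largest changes per direction with adjusted p under 0.05 and arrays that did not overlap between the groups, and up to 4 members of each list with the smallest p among those past the threshold. CDKN1A, ABCB1, EIF4E and MKI67 were named whatever their result. The position of the AD32 4E-BP1 array was the median, over called genes changed at least 2-fold, of its difference from the A549 DMSO mean as a share of the AD32 difference. Each AD32 array was left out in turn from both the choice of genes and the AD32 mean, and was itself measured the same way.

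Alternatives were a further quantile normalization, median centring, removal of the lowest 33.3% of genes by mean, a trended robust prior, array weights, a fit of the compared groups alone, the mean of a gene's probe sets, the replicate number as a block, each replicate left out, and a test against a minimum fold of 1.5. Pseudocounts did not apply to log2 values. Added after seeing the data were the averaging of A549 DMSO replicates 3 and 4, which were nearly identical, and the removal of A549 DMSO replicate 1 or AD32 replicate 3 from the pooled spread. A change of sign was counted as a reversal only where the reported or the alternative value passed the threshold. Chromosomal windows held 25 neighbouring expressed genes on numbered chromosomes 1 to 22, and 1000 shuffles of gene order gave the limit for a window's median. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables, windows and plots.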

Results

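Transcript levels were compared among cells that respond differently to discodermolide, a natural product that binds and stabilises microtubules. A549 is a human lung adenocarcinoma line, labelled sensitive in DMSO and senescent after discodermolide. AD32 is labelled resistant and was grown in the drug at 32 nM. AD32 4E-BP1 carries the name of 4E-BP1, the repressor of cap-dependent translation encoded by EIF4EBP1, and is labelled sensitive. The groups held 4 arrays of A549 in DMSO, 2 of A549 in discodermolide, 3 of AD32 and 1 of AD32 4E-BP1. All levels are log2 signals as deposited, and all adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment. Folds are ratios of signal. Many of the largest have 1 group near or below the lower quartile of the arrays (4.77 to 4.94), where signal above background was not shown, so they need not equal ratios of transcripts.

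EIF4EBP1 was examined first because it names a line. Its level was 9.68 ± 0.37 (SD, n = 4) in A549 in DMSO and 9.67 ± 0.13 (SD, n = 2) in A549 in discodermolide. In AD32 it was 8.52 ± 0.48 (SD, n = 3), and the AD32 4E-BP1 array stood at 11.61. Against A549 in DMSO, EIF4EBP1 in AD32 fell by 1.16 on the log2 scale (SE 0.26, adjusted p = 0.0326), with all 3 AD32 arrays below all 4 A549 DMSO arrays. Against AD32, the AD32 4E-BP1 array was 8.52-fold higher (log2 difference 3.09, SE 0.39, adjusted p = 0.00708). It lay 1.93 above the A549 DMSO mean (SE 0.38) and above all 4 A549 DMSO arrays, the highest being replicate 1 at 10.23. This excess did not pass the threshold, and neither did any other gene in that comparison of a lone array. The AD32 call ended without AD32 replicate 2 (adjusted p = 0.108) and without A549 DMSO replicate 2, 3 or 4 (0.0606, 0.0676 and 0.0759). It also ended after a further quantile normalization (adjusted p = 0.07) and with only the 2 groups fitted (0.0619), and over all alternatives its adjusted p ran from 0.00401 with array weights to 0.763 against a minimum fold. For AD32 4E-BP1 against AD32 it ran from 0.000111 to 0.15, and the call ended with only the 2 groups fitted. With array weights the excess over A549 in DMSO passed (adjusted p = 0.00869).

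**Figure D1:**
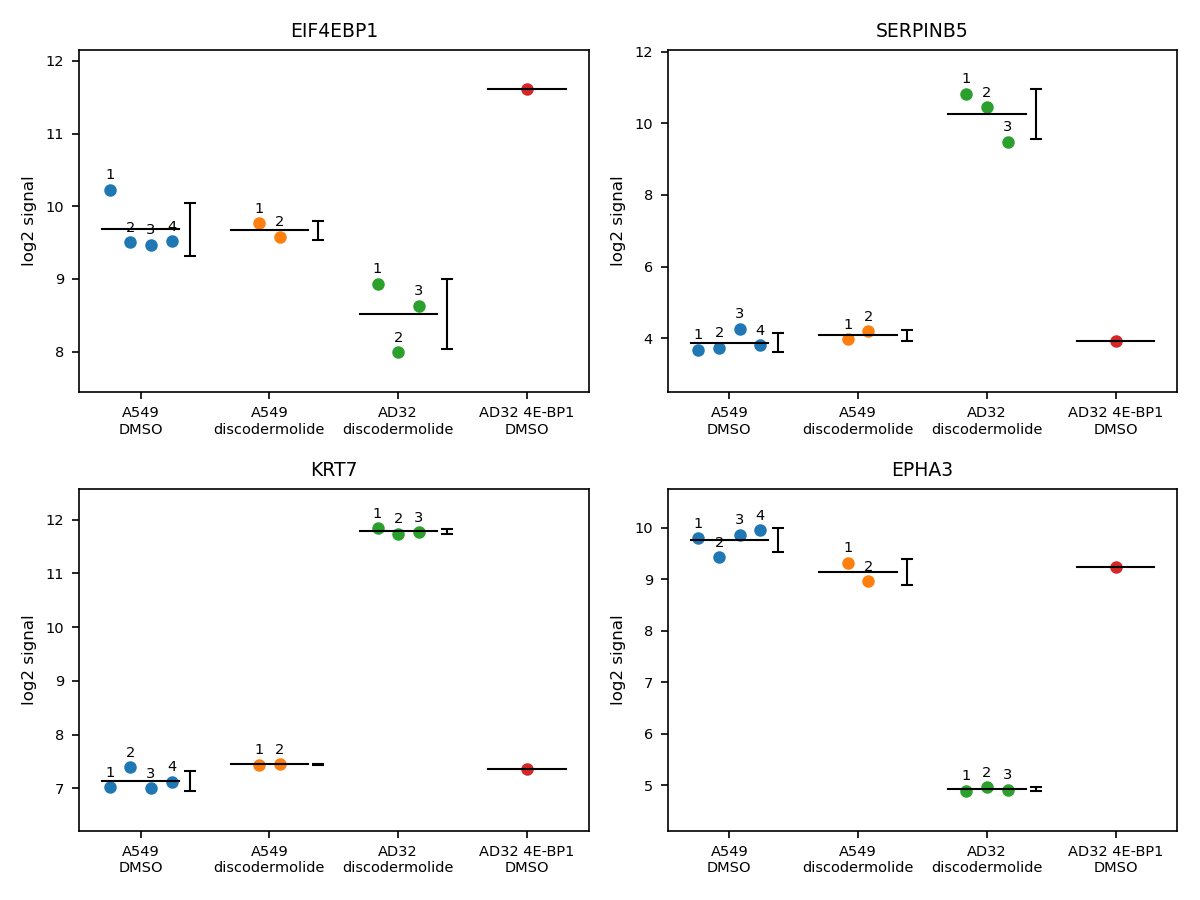
Log2 signal of EIF4EBP1, SERPINB5, KRT7 and EPHA3 on each array, by group, with replicate numbers beside the points, a line at the group mean and a bar of ± 1 SD where a group has over 1 array. EIF4EBP1 is lowest in AD32 and highest on the AD32 4E-BP1 array (11.61), whereas that array lies with A549 for SERPINB5 (3.92), KRT7 (7.35) and EPHA3 (9.23).

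Discodermolide treatment of A549 asks how the sensitive line responds to the drug. CFI, encoding complement factor I, rose 14.5-fold (log2 difference 3.86, SE 0.35, adjusted p = 0.004). LBP, the lipopolysaccharide-binding protein, rose 8.98-fold (SE 0.15 on the log2 scale, adjusted p = 7.4e-05), and SULF2, an extracellular heparan sulfatase, rose 6.59-fold (SE 0.16, adjusted p = 0.000246). VTN (vitronectin) rose 4.74-fold, ABAT (a GABA transaminase) 4.75-fold, TM4SF20 6.27-fold and the small heat shock protein gene CRYAB 7.39-fold. In all, 68 of 18279 genes differed, 64 higher and 4 lower. That balance moved to 462 higher and 181 lower without A549 DMSO replicate 1, and to 2707 and 1866 with array weights. The falls were H3C11 and H1-4, which encode histones of the replication-dependent clusters (7.14-fold and 3.30-fold), RFLNB (2.78-fold) and CACNB2 (2.16-fold). All 4 falls lost their call when either treated array was left out (12 higher and 0 lower without replicate 1, 8 and 0 without replicate 2). H3C11 and CACNB2 also lost it without A549 DMSO replicate 2, 3 or 4, and RFLNB without A549 DMSO replicate 4.

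The p53 target genes rose as a list in treated A549. All 28 measured members were higher, with a median log2 difference of 1.09. Over all genes 4 members passed the threshold, namely SPATA18 (4.94-fold), SESN1 (3.83-fold), EDA2R (2.82-fold) and DDB2 (1.92-fold), and 22 did when adjusted over the list alone. Camera gave adjusted p = 2.65e-20 at the preset correlation and adjusted p = 0.16 with an estimated correlation, while fry gave 0.00568. CDKN1A, which encodes the cell cycle inhibitor p21, was higher by 1.76 on the log2 scale but did not pass (SE 0.42, adjusted p = 0.133).

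Lysosomal, interferon-stimulated, mesenchymal and secretory lists were also called higher at the preset correlation in treated A549. Lysosome genes had a median log2 difference of 0.75, with 21 of 22 higher, 0 called over all genes and 12 called adjusted over the list alone (adjusted p = 0.23 with an estimated correlation). On A549 DMSO replicate 1 the lysosome list mean was 10.02, between the other DMSO arrays (9.37 to 9.46) and the treated arrays (both 10.28). Among 30 interferon-stimulated genes the median was 0.63 and 2 were called, TRIM22 (8.41-fold) and SAMD9 (4.27-fold), with 10 called adjusted over the list alone (adjusted p = 0.349 with an estimated correlation). The treated arrays had interferon list means of 6.39 and 7.68, and A549 DMSO replicate 1 (6.41) lay above the lower of them, with the other DMSO arrays at 5.83 to 5.88. Mesenchymal markers had 2 called genes of 25, ACTA2 (smooth muscle actin, 6.78-fold) and SNAI2 (a repressor of epithelial genes, 2.53-fold), with 3 called adjusted over the list alone and adjusted p = 0.185 with an estimated correlation. The mesenchymal list was not called without A549 DMSO replicate 1 (adjusted p = 0.0515). Senescence-associated secretory factors had a median of 0.29, with 0 of 32 called over all genes and 4 adjusted over the list alone (adjusted p = 0.349 with an estimated correlation), and the list was not called without discodermolide replicate 2 (adjusted p = 0.0558).

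Proliferation genes were lower in treated A549, but not beyond the spread among the DMSO arrays. All 30 G2/M and mitosis genes lay lower, with a median log2 difference of -2.43, and 33 of 34 S phase genes did, with a median of -1.72. In neither list did any gene pass, over all genes or adjusted over the list alone. Camera called both lists lower at the preset correlation (adjusted p = 6.66e-14 and 1.01e-12) and neither with an estimated correlation (adjusted p = 0.349 and 0.386). On A549 DMSO replicate 1 the G2/M list mean was 6.76, as on the treated arrays (6.57 and 6.79), against 9.84 to 9.93 on the other 3 DMSO arrays. MKI67, which encodes the proliferation marker Ki-67, was 9.21 ± 1.89 (SD, n = 4) in DMSO and 6.90 in discodermolide (adjusted p = 0.599). Ribosome biogenesis genes were lower in 20 of 21 cases, with a median of -0.44 and 0 called, and adjusted p = 0.464 with an estimated correlation. The count of 68 genes rose to 643 without A549 DMSO replicate 1, all 68 kept. Without A549 DMSO replicate 2, 3 or 4 it was 16, 15 or 12, and without discodermolide replicate 1 or 2 it was 12 or 8.

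**Figure D2:**
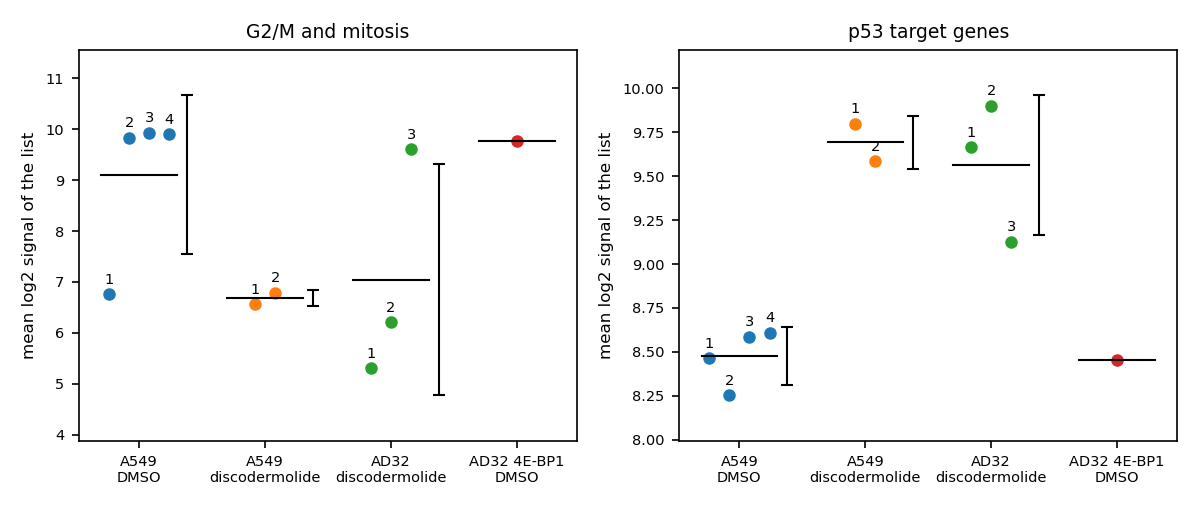
Mean log2 signal of the G2/M and mitosis list and of the p53 target list on each array, by group, with replicate numbers, group means as lines and bars of ± 1 SD where a group has over 1 array. A549 DMSO replicate 1 lies low in the mitosis list (6.76) and with the other DMSO arrays in the p53 list (8.46), and AD32 replicate 3 lies high in the mitosis list (9.61).

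The comparison of AD32 with A549 in DMSO sets resistance together with growth in the drug against a sensitive line in DMSO. SERPINB5 (maspin) was 83.7-fold higher (log2 difference 6.39, SE 0.29, adjusted p = 8.88e-06), and MAGEB2, a cancer-testis antigen gene, 64.2-fold (SE 0.23, adjusted p = 3.18e-06). CEACAM6, an adhesion molecule, was 45.8-fold higher, and GDA, guanine deaminase, 36.7-fold. SLPI, a secreted protease inhibitor, was 30.3-fold higher, TSPAN8 29.3-fold, CLTRN 26.2-fold and F5 (coagulation factor V) 26.0-fold. TXNIP, which encodes a thioredoxin-binding protein, was uneven in AD32 (9.81 ± 2.32, SD, n = 3, against 5.11 ± 0.34, SD, n = 4). Its 26.0-fold rise was 65.3-fold without AD32 replicate 3 and was not called without replicate 2 (log2 difference 3.905, adjusted p = 0.0553). The rise of CEACAM6 was 71.2-fold without AD32 replicate 3 and that of GDA 23.3-fold without AD32 replicate 1. KRT7, the simple-epithelial keratin 7, was higher by 4.65 on the log2 scale with little spread, at 11.78 ± 0.05 (SD, n = 3) against 7.13 ± 0.19 (SD, n = 4).

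Several receptors, enzymes and secreted proteins of A549 were low in AD32. NTS, the neurotensin precursor gene, fell 73.1-fold (SE 0.53 on the log2 scale, adjusted p = 0.000244), and the ephrin receptor genes EPHA3 and EPHA5 fell 28.4-fold and 10.2-fold. KCNE4 fell 14.8-fold, the channel gene TRPA1 13.9-fold, FGL1 12.7-fold, BCHE (butyrylcholinesterase) 11.8-fold, TRHDE 11.7-fold and the lysosomal enzyme gene GALC 11.3-fold. APOH, encoding a plasma apolipoprotein, fell by 3.80 on the log2 scale (SE 0.58). Without AD32 replicate 3 the fall of APOH was 22.8-fold, without AD32 replicate 2 that of NTS was 117-fold, and without A549 DMSO replicate 1 that of FGL1 was 6.86-fold. In all, 1045 genes differed, 644 higher and 401 lower, of which 385 and 216 changed at least 2-fold. The excess of higher genes was absent without A549 DMSO replicate 1 (1041 higher and 1123 lower) and with array weights (2037 and 2178).

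Epithelial markers rose as a list in AD32, with 5 of 24 called over all genes and 7 adjusted over the list alone, and 0 called lower. They included JUP (3.04-fold), DSP (2.27-fold) and CDH1 (E-cadherin, 2.17-fold) (camera adjusted p = 1.39e-05, and adjusted p = 0.514 with an estimated correlation). Mesenchymal markers went both ways. SNAI2, SERPINE2 and ACTA2 rose 2.80-fold, 3.29-fold and 3.86-fold and ZEB1 fell 2.07-fold, with 4 of 25 higher and 1 lower. In the alveolar and airway list FOXA1 (1.99-fold) and CEACAM6 were called, and among fibroblast markers FBN1 rose 5.56-fold and COL3A1 fell 4.23-fold. Leukocyte and endothelial markers had 0 of 14 called.

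The p53 target genes were higher in AD32 too, with 11 of 28 called over all genes and 22 higher and 1 lower adjusted over the list alone. MDM2, the p53 ubiquitin ligase gene, rose 3.08-fold, SESN1 3.29-fold, AEN 2.99-fold, DDB2 2.41-fold and CDKN1A 3.19-fold (adjusted p = 0.0309). The list's median was 1.08, with adjusted p = 0.216 with an estimated correlation and 0.0108 by fry. NRF2 target genes, the antioxidant and detoxification set, had 3 of 26 lower and 0 higher over all genes, and 11 lower and 1 higher adjusted over the list alone. EPHX1 fell 2.83-fold, ALDH1A1 1.92-fold and AKR1C1 1.86-fold (list adjusted p = 0.528 with an estimated correlation). AD32 replicate 3 (NRF2 list mean 10.93) lay within the A549 DMSO arrays (10.90 to 11.04), and replicates 1 and 2 lay at 10.34 and 10.02. Hypoxia and glycolysis genes had 6 of 20 lower and 0 higher, among them ALDOC (3.74-fold), CA12 (2.82-fold), P4HA1 (1.83-fold) and BNIP3 (1.63-fold), with adjusted p = 0.216 with an estimated correlation and 0.0161 by fry.

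Among genes tied to the study's question, ABCG2, a drug efflux transporter gene, fell 3.96-fold in AD32 and was the only one of 13 transporter genes called over all genes. ABCB1, which encodes P-glycoprotein, was 4.45 ± 0.03 (SD, n = 3) against 4.37 ± 0.07 (SD, n = 4) and did not differ detectably (adjusted p = 0.789). Both levels lay below the lower quartile of every array (4.77 to 4.94), where signal above background was not shown, so a difference could be missed. In the cap-dependent translation and mTOR list, EIF4E3 rose 4.84-fold and MKNK2, a kinase of eIF4E, 2.34-fold, EIF4EBP1 fell, and the other 22 of 25 genes were not called. EIF4E itself differed by 0.17 on the log2 scale (SE 0.16, adjusted p = 0.678). Microtubule-associated genes MAP1B (2.11-fold) and CLIP1 (1.81-fold) rose and SPAST, which encodes the severing enzyme spastin, fell 1.94-fold. None of 19 tubulin and tubulin cofactor genes was called. The chemokine genes CXCL1, CXCL2 and CXCL8 rose 9.47-fold, 5.18-fold and 3.85-fold, while IGFBP4 fell 2.32-fold and the secretory list as a whole was not called (adjusted p = 0.102).

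Smaller groups in AD32 are given here in brief. Neighbours of EIF4EBP1 on chromosome 8 were lower as a list (median -0.29, 2 of 23 called), led by UNC5D (3.90-fold) and ASH2L (1.57-fold), with adjusted p = 0.216 with an estimated correlation and 0.0161 by fry, and not called without AD32 replicate 3 (adjusted p = 0.0624). Among interferon-stimulated genes SAMD9 rose 15.1-fold and OAS1 2.92-fold while HERC5 fell 10.2-fold. Apoptosis genes included a rise of BCL2L1 (2.19-fold) and a fall of BCL2L11 (1.74-fold). The immediate-early genes ATF3, JUN and IER3 rose 2.37-fold, 2.01-fold and 1.83-fold, the lysosomal cholesterol transporter gene NPC1 2.34-fold, and PMVK fell 1.36-fold. Endoplasmic reticulum and amino acid stress genes had 0 of 26 called.

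Mitotic transcripts differed among the AD32 arrays themselves. The G2/M list mean was 5.30 and 6.21 on replicates 1 and 2 and 9.61 on replicate 3, and 0 of 30 genes were called (list median -2.17, adjusted p = 0.601 with an estimated correlation). The S phase and ribosome biogenesis lists were also called lower only at the preset correlation (medians -1.05 and -0.47, adjusted p = 0.602 and 0.601 with an estimated correlation), and neither without AD32 replicate 1 (adjusted p = 0.105 for both). The count of 1045 genes was 1965 without AD32 replicate 3 and 2164 without A549 DMSO replicate 1. It was 571 and 522 without AD32 replicates 1 and 2, and 531 and 512 without A549 DMSO replicates 3 and 4.

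AD32 and A549 were next compared in the same concentration of drug. The AD32 genes SERPINB5 (72.4-fold), MAGEB2 (56.5-fold), GDA (42.6-fold), CEACAM6 (39.4-fold), TC2N (27.2-fold), CLTRN (25.5-fold), F5 (24.6-fold), FSTL1 (21.5-fold), KRT7 (20.2-fold) and TSPAN8 (18.1-fold) were higher in AD32 than in treated A549. FGL1 (50.3-fold), CRYAB (33.4-fold), APOH (32.4-fold), KCNE4 (23.8-fold), NTRK3 (19.4-fold), EPHA3 (18.6-fold), BCHE (16.5-fold), GALC (15.2-fold) and CFI (adjusted p = 0.000598) were lower. Without AD32 replicate 3 CEACAM6 was 61.4-fold higher and APOH 52.8-fold lower, and without AD32 replicate 1 GDA was 27.1-fold higher. In all, 683 genes differed, 234 higher and 449 lower. CDKN1A (log2 difference -0.09, SE 0.44, adjusted p = 0.969) and EIF4EBP1 (-1.15, SE 0.31, adjusted p = 0.0841) did not pass.

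Interferon-stimulated genes were lower in AD32 than in treated A549, with 5 of 30 lower and 1 higher. IFI44L was 22.6-fold lower, though its treated arrays differed widely (8.98 ± 2.18, SD, n = 2) and it was 65.9-fold and 7.76-fold lower without treated replicate 1 and 2, HERC5 14.7-fold and TRIM22 7.00-fold, while SAMD9 was 3.53-fold higher. The hypoxia list had 4 of 20 lower, among them ALDOC (5.72-fold) and BNIP3 (2.51-fold), and the NRF2 list 2 of 26, EPHX1 (6.29-fold) and ALDH1A1 (2.15-fold). The lysosome list had 1 of 22 lower, FUCA1 (3.81-fold), and 11 adjusted over the list alone. Epithelial markers were the called list that lay higher (1 of 24 called over all genes, KRT7). With an estimated correlation these 5 lists had adjusted p = 0.612, 0.181, 0.612, 0.612 and 0.612 in the order given here. The microtubule plus-end gene MAPRE3 was 5.55-fold and the neuronal microtubule protein gene MAP2 3.72-fold lower in AD32, and the p53 target SPATA18 7.64-fold lower, whereas the p53 list as a whole had a median of 0.07 and was not called (adjusted p = 0.86).

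Secretory genes IL6 (2.59-fold), LIF (2.79-fold) and IGFBP4 (2.93-fold) were lower in AD32 than in treated A549, and CXCL1 was 5.55-fold higher. The count of 683 genes was 1082 without AD32 replicate 3 and 412 and 420 without AD32 replicates 1 and 2. It was 186 and 132 without discodermolide replicates 1 and 2, which leaves a lone treated array.

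The responses of A549 and AD32 against the shared A549 DMSO arrays were set side by side. Across genes, which are not independent replicates, their log2 differences correlated at r = 0.444, against 0.379 on average and 0.414 at most in 200 simulations of unchanged groups. The covariance was 0.108 against a simulated 0.033. The simulations drew each gene independently, whereas genes of a list varied together (estimated correlation 0.971 for G2/M and mitosis). Their range of r is therefore too narrow to judge the observed value. With the controls split into separate pairs in all 6 ways, r lay between 0.190 and 0.380 and the covariance between 0.056 and 0.091. The simulated values were made with shared controls and are no reference for these splits, whose responses share no control array. Unchanged groups were not simulated with split controls. Called genes higher in both numbered 19, where independent lists would share 2.3, and 1 was lower in both and 5 opposed. They included SAMD9, SNAI2, ACTA2, SESN1 and DDB2. With split controls 15 genes were higher in both where A549 DMSO replicates 3 and 4 served treated A549, and 1 or 2 in every other split. Treated A549 had 139 called genes in the former and 6 to 9 in the others.

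AD32 4E-BP1, labelled sensitive, was compared with its resistant namesake, and here line and drug differ together and the first group is 1 array. Many genes with large differences in AD32 were near A549 levels on this array. NTS read 7.62, near A549 in discodermolide at 7.51 ± 0.04 (SD, n = 2) and between AD32 at 4.60 ± 1.21 (SD, n = 3) and A549 in DMSO at 10.79 ± 0.64 (SD, n = 4). Against these last it passed the threshold in neither case by limma (adjusted p = 0.186 and 1). MAGEB2 was 82.0-fold lower than in AD32 (log2 difference -6.36, SE 0.35, adjusted p = 0.000105), SERPINB5 81.0-fold, GDA 39.3-fold, CLTRN 31.8-fold, TC2N 27.3-fold, TSPAN8 23.8-fold, SCEL 23.3-fold, FSTL1 22.4-fold and KRT7 21.5-fold, and SLPI fell by 4.32 on the log2 scale. Without AD32 replicate 1 GDA differed by -4.645 on the log2 scale and without AD32 replicate 3 SCEL was 40.7-fold lower. EPHA3 was 19.7-fold higher, NTRK3 14.9-fold, GALC 13.4-fold, TRHDE 11.3-fold, EPHA5 11.1-fold, PART1 11.1-fold, LRRCC1 10.8-fold, HERC5 10.1-fold, P4HA3 9.91-fold and BCHE 8.77-fold. In all, 168 genes differed, 62 higher and 106 lower.

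Among the lists, p53 targets lay lower on the AD32 4E-BP1 array than in AD32 in 26 of 28 cases (median -1.15), with DDB2 called (1.79-fold) and 16 genes adjusted over the list alone. G2/M genes lay higher in 30 of 30 cases (median 2.74) and S phase genes in 34 of 34 (median 1.63), with 0 called, although AD32 replicate 3 (list means 9.61 and 9.59) lay close to the array (9.77 and 9.60). CXCL1 (9.20-fold), SAMD9 (12.6-fold) and EIF4E3 (4.48-fold) were lower, and UNC5D (3.17-fold) and BCL2L11 (2.38-fold) were higher. Camera called 10 of 23 lists at the preset correlation, and 0 with an estimated correlation (adjusted p = 0.507 for p53 targets and 0.524 for G2/M) and 0 by fry. The gene count was 656 without AD32 replicate 3, whose G2/M level was the highest of the 3, and 13 with only the 2 groups fitted.

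Against A549 in DMSO, the AD32 4E-BP1 array differed in 0 of 18279 genes by limma. At an unadjusted p under 0.05 there were 208 genes, where 914 would be reached by chance, and array weights gave 3 calls. In simulations with 200 changed genes, each drawn independently, 65% of genes changed by 2 on the log2 scale were called. That share need not hold here, where unadjusted p-values under 0.05 were fewer than by chance. EIF4EBP1, at 1.93 above A549 in DMSO, was not called. CDKN1A differed by -0.23 on the log2 scale (SE 0.54), and the levels of ABCB1 (4.21 against 4.37 ± 0.07, SD, n = 4) and EIF4E (5.52 against 5.49 ± 0.28, SD, n = 4) were close. Both ABCB1 levels lay below the lower quartile of every array, where signal above background was not shown. Over all genes the array correlated with A549 DMSO replicate 2 at r = 0.995, with 50 genes over 2-fold apart, and with A549 DMSO replicates 3 and 4 at 0.988, with 200 and 196. A549 DMSO replicate 1 was farther (r = 0.957, 1613 genes) than AD32 replicate 3 (r = 0.979, 613 genes), and AD32 replicates 1 and 2 lay at 0.932 and 0.939. Endoplasmic reticulum stress genes were lower in 24 of 26 cases (median -0.54) and cholesterol biosynthesis genes in 15 of 18 (median -0.32), neither called with an estimated correlation. The A549 DMSO arrays themselves spread widely in both lists. For stress genes the array's list mean was 9.165, against 9.307 on DMSO replicate 2 and up to 10.206 on replicate 1. For cholesterol genes it was 8.674, against 8.757 on DMSO replicate 1 and up to 9.224 on replicate 3. Neighbours of EIF4EBP1 were also called lower at the preset correlation, and the mitosis, S phase, mesenchymal and cap-dependent translation lists higher, and 0 of the 7 lists held with an estimated correlation. Without A549 DMSO replicate 1 the medians of the mitosis and S phase lists turned negative (-0.155 and -0.035), the array (9.77) lying below the other 3 DMSO arrays (9.84 to 9.93) for mitosis. The cap-dependent translation list was not called without A549 DMSO replicate 1 or 4 (adjusted p = 0.248 and 0.0563).

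On a scale from 0 at the A549 DMSO mean to 1 at the AD32 mean, the AD32 4E-BP1 array lay at 0.036, averaged over 3 choices of genes that each left out an AD32 array. The left-out AD32 arrays lay at 0.957, 1.038 and 0.438 for replicates 1, 2 and 3, with an SD of 0.326. These values rest on different genes, 430, 380 and 1151 in the same order, and their SD comes mostly from replicate 3. That SD does not measure the spread of the AD32 4E-BP1 array or of single A549 arrays, so it sets no bound for the array. Its position is descriptive, and no test was made of it.

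**Figure D3:**
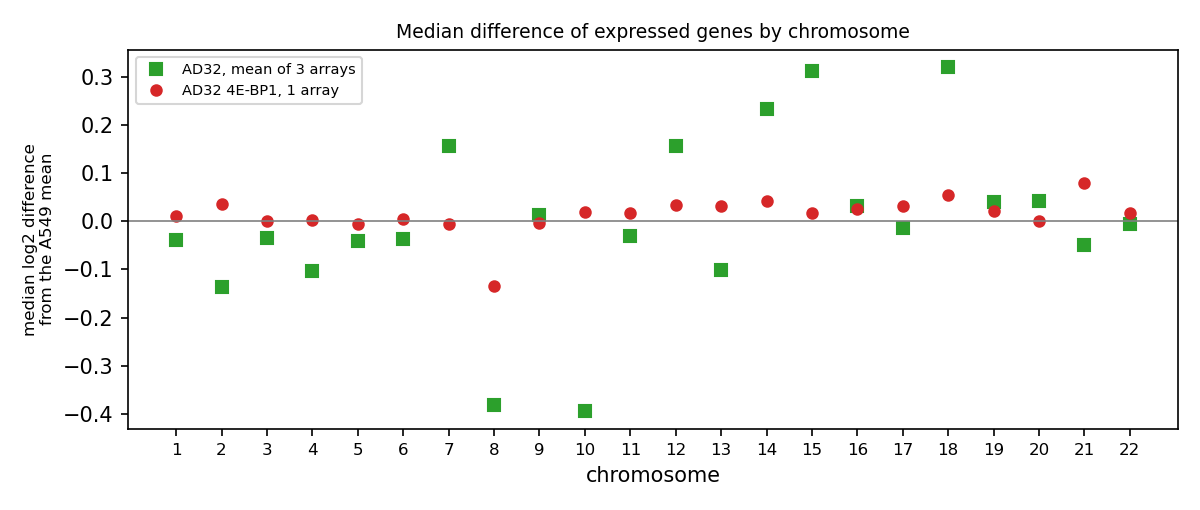
Median log2 difference from the mean of the 6 A549 arrays over expressed genes of each numbered chromosome, for the mean of the 3 AD32 arrays (squares) and for the AD32 4E-BP1 array (circles), with a line at 0. AD32 is lowest on chromosomes 10 (-0.395) and 8 (-0.381) and highest on 18 (0.320) and 15 (0.312), where the AD32 4E-BP1 array lies at 0.019, -0.135, 0.055 and 0.017.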

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

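The tests of A549 DMSO replicate 1 and of a uniform chromosome 8 shift for EIF4EBP1, and the count of other splits, were chosen after the result was seen. A sample was singled out when its distance from the nearest of the other 3 A549 DMSO arrays was extreme for its group's range. Of 119 lists and genes examined, 25 showed such a sample, and in 17 of the 25 it was A549 DMSO replicate 1. Chance gives about 1 in 20, or 6.0 here, for independent items that were not chosen from the data. Here 96 items were named genes, most of them chosen on these same arrays, and many items vary together. The 6.0 is therefore no firm reference for the 25.

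On that array the list mean was low for G2/M and mitosis (6.761), S phase (6.954), tubulins (8.618) and ribosome biogenesis (8.991). It was high for lysosome (10.019), interferon-stimulated genes (6.407), immediate-early genes (8.229) and leukocyte and endothelial markers (5.322). Single genes set apart on it were CRYAB (8.200), EIF4EBP1 (10.226), EPHA5 (7.510), H3C11 (11.506), HERC5 (7.543), LRRCC1 (6.913), MAP2 (7.903), TSPAN8 (4.007) and TXNIP (5.613). On A549 DMSO replicate 2 the NRF2 list mean (11.038) and ALDH1A1 (13.334), BCHE (8.477), DSP (9.220), IFI44L (5.286) and NTS (11.735) stood apart, and on replicate 4 BCL2 (6.037) and UNC5D (8.171).

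A549 DMSO replicate 1 is low in mitotic transcripts although it is labelled DMSO. A discodermolide-treated sample under the wrong label would carry the p53 response as well, but on a scale from 0 at the other DMSO arrays to 1 at the treated arrays, replicate 1 lay at -0.016 for p53 targets and at 0.974 for mitosis, which argues against treatment like that of those arrays. Over all genes, however, it lay closer to the treated arrays (r = 0.9760 and 0.9740) than to DMSO replicates 2, 3 and 4 (0.9537, 0.9484 and 0.9510). A processing step or culture day shared with AD32 replicate 1 stays open. Over 9983 genes that did not follow the mitosis list, the deviation of A549 DMSO replicate 1 correlated with AD32 replicate 1 minus replicate 2 at 0.367. The correlation was 0.146 for AD32 replicate 1 minus replicate 3 and -0.212 for AD32 replicate 2 minus replicate 3. These genes were chosen by their correlation with the mitosis list over the same arrays. AD32 replicate 3 differs from the other AD32 arrays in that list, so the values involving it cannot be set against 0.367. A549 DMSO replicate 1 and AD32 replicate 1 also had the 2 lowest upper quartiles of signal (8.142 and 8.249). The design names no biological difference among the DMSO arrays, and none was tested.

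The AD32 arrays are split in the same way, since replicate 3 alone has high mitotic transcripts. The 7 AD32 and A549 DMSO arrays can be split into 3 and 4 in 35 ways. Of these splits, 2 called at least as many genes as the real one (1045), the real one included. By this count alone chance was not excluded at the 0.05 level. The highest of the others, 2828, set AD32 replicates 1 and 2 with A549 DMSO replicate 1 against the rest, which points to a structure of the arrays, these 3 being the ones low in mitotic transcripts. The split that set A549 DMSO replicates 2, 3 and 4 against the rest called 614, and every remaining split called 0.

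EIF4EBP1 lies on chromosome 8, whose 429 expressed genes had a median log2 difference of -0.338 between AD32 and A549 in DMSO, against -1.163 for EIF4EBP1. In units of the gene's own standard error it lay at -3.20 from that median, and at -2.20 without AD32 replicate 2 and -2.61 without A549 DMSO replicate 1, which argues against a uniform shift of the chromosome as the whole account. The genes scatter widely, however, and 42 of the 429 (9.8%, against 3.2% of all expressed genes) were as low as EIF4EBP1, so a chromosome 8 difference that varies along its genes stays open. With single replicates left out the 9.8% ran from 5.1% to 20.3%. Discodermolide moved EIF4EBP1 by -0.009 in A549 (SE 0.293), and AD32 differed by -1.154 (SE 0.309) from A549 in the drug. These values argue against a drug response like that of A549. Regulation of the gene in AD32 and an effect of the drug particular to AD32 stay open and were not tested.

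Probe sets with several gene names or none were outside the gene counts. Of these, 48 differed between A549 in discodermolide and DMSO, 58 between AD32 and A549 in DMSO, 37 between AD32 and A549 in discodermolide and 4 between AD32 4E-BP1 and AD32.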

How the results depend on the processing

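The averaging of A549 DMSO replicates 3 and 4 and the removal of an array from the pooled spread were chosen after the data were seen. Counts are given in the order A549 in discodermolide against DMSO, AD32 against A549 in DMSO, AD32 against A549 in discodermolide and AD32 4E-BP1 against AD32, as reported 68, 1045, 683 and 168. Array weights gave 4573, 4215, 1869 and 1282, and 3 in place of 0 for AD32 4E-BP1 against A549 in DMSO. The weights ranged from 0.18 for A549 DMSO replicate 1 to 4.64 for A549 DMSO replicate 4. A minimum fold of 1.5 gave 9, 166, 153 and 65, being a stricter hypothesis. Leaving out each replicate gave 8 to 643, 512 to 2164, 132 to 1082 and 113 to 656, and 0 throughout for AD32 4E-BP1 against A549 in DMSO. Only the 2 groups compared gave 106 for treated A549 against DMSO, 353 for AD32 against treated A549 and 13 for AD32 4E-BP1 against AD32. Removing the 33.3% of genes with the lowest mean gave 36 for treated A549 against DMSO and 107 for AD32 4E-BP1 against AD32. Averaging A549 DMSO replicates 3 and 4, which have 1 gene over 2-fold apart (r = 0.9974), gave 15 for treated A549 and 525 for AD32 against DMSO and 99 for AD32 4E-BP1 against AD32. Taking AD32 replicate 3 out of the pooled spread gave 134 for treated A549 against DMSO. Taking A549 DMSO replicate 1 out gave 1215 for AD32 against treated A549 and 262 for AD32 4E-BP1 against AD32. Apart from settings whose construction gives the reason, the cause was not tested.

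The replicate numbers showed no consistent pairing of the samples. Deviations of AD32 and A549 DMSO arrays with the same number correlated at 0.677, -0.264 and 0.411 for replicates 1, 2 and 3. AD32 replicates 2 and 3 correlated better with another number than with their own. The 0.677 was the highest of all pairs and joins 2 arrays low in mitotic transcripts. Pairing was therefore neither shown nor excluded. With the replicate block the first 3 counts were 4, 650 and 547, and the comparisons of AD32 4E-BP1, which has no number, were not run.

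Gene lists called at the preset correlation numbered 8, 8, 5, 10 and 7 over the 5 comparisons. With an estimated correlation they numbered 0 in each, and by fry 2, 6, 1, 0 and 0. With the design columns in another order, tried after the result was seen, the last fry count was 1, mesenchymal markers moving from an adjusted p of 0.063 to 0.0427, and the other counts stayed. Without A549 DMSO replicate 1, 14 were called for AD32 against A549 in DMSO and 4 for AD32 4E-BP1 against A549 in DMSO, where array weights also gave 4. Leave-one-out counts ran from 6 to 14 and from 4 to 8 for these. Direction turned for the G2/M list in AD32 against treated A549 without AD32 replicate 3 (median -0.928, from 0.303, with others left out up to 1.159). Against A549 in DMSO, the AD32 4E-BP1 array turned to -0.118 with array weights and -0.155 without A549 DMSO replicate 1 for G2/M, and to -0.035 without that replicate for S phase, where leaving out others gave up to 0.895 and 0.854.

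The correlation of the A549 and AD32 responses was 0.444 with shared controls. With split controls, where the responses share no array, it was 0.288, 0.380, 0.361, 0.233, 0.249 and 0.190. The position of the AD32 4E-BP1 array stayed between -0.007 and 0.103 in each alternative run. Among named genes, 0 calls changed direction, 464 gene and setting pairs lost the threshold, 10 gained it and 2338 stayed on their side. With each replicate left out in turn, 3 of 19, 41 of 65, 22 of 45 and 21 of 27 named calls stayed past the threshold, among them LBP, SULF2 and VTN in the first and KRT7, EPHA3, MAGEB2 and SERPINB5 in the other 3. The values carry no measure of signal over background, so low levels set no limit that could be tested.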

Other observations

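The test on genes not moved by the drug was chosen after the result was seen, and for the test on chromosomal windows the bound was set before any window value but the window size and shuffled limit were settled after a first look at windows. Genes named only as window borders were chosen after their values were seen.

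Neighbouring genes differed together between AD32 and the 6 A549 arrays. Of 459 windows of 25 expressed genes, 37 had a median beyond 0.402 on the log2 scale, the limit from 1000 shuffles of gene order, 28 lower and 9 higher in AD32. Chromosome 10 held 11 of them and chromosome 8 held 10, and the medians over all expressed genes were -0.395 for chromosome 10 and -0.381 for chromosome 8. Chromosomes 18, 15 and 14 lay higher, at 0.320, 0.312 and 0.233. The lowest window ran from E2F5 to DPY19L4 on chromosome 8 (-0.92), and the highest from SREK1 to NSA2 on chromosome 5 and from GOLM2 to AP4E1 on chromosome 15 (both 0.54). Whether DNA copy number differs was not measured.

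The AD32 4E-BP1 array lay near A549 for most genes that set AD32 apart. Removal of the discodermolide response that A549 shows would leave AD32 levels at genes the drug does not move, but over 227 such genes the median position was -0.002 (quartiles -0.101 and 0.117), which argues against it as the whole account. Cells not derived from AD32 would lack its chromosomal differences, and in the 37 windows the array lay at a median position of 0.093 (quartiles -0.069 and 0.277), within the bound of 0.25. In 42, 44 and 18 windows chosen without AD32 replicate 1, 2 or 3 it lay at 0.122, 0.1 and -0.033 and the left-out AD32 array at 1.078, 0.67 and 0.638, while A549 DMSO replicate 1 lay at 0.105, 0.386 and 0.305, so the position of an A549 array can itself pass the bound. Since line and drug change together on 1 array, that explanation stays open, as do an effect of 4E-BP1 and growth without the drug. So does a subline of AD32 that lost or never had these differences. The array's chromosome 8 median (-0.135) was its lowest, its other chromosomes lying between -0.006 (chromosome 7) and 0.079 (chromosome 21). Among single A549 arrays only DMSO replicate 1 (-0.144) lay as low on chromosome 8. That replicate was low on other chromosomes too, such as chromosome 4 (-0.247). The other A549 arrays ran from 0.008 to 0.043 on chromosome 8, with the AD32 mean at -0.381. Whether the array shares part of the AD32 difference on chromosome 8 stays open and was not tested.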
